A study of Homo sapiens with 16 samples.

How the data were processed

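RNA was measured by RNA-seq in 16 libraries of 2 human breast cancer cell lines, MDA-MB-231 and MCF7, transfected with control siRNA (siCtrl) or with an siRNA pool against NUP93 (siNUP93). Per the labels' protocols, poly(A) RNA was made into libraries with the Lexogen SENSE kit, the siRNAs were transfected with Lipofectamine 2000, and the MCF7 cells were extracted whole (whole-cell extract) or separated into cytosolic and nuclear fractions. Per the submitters' processing notes, the tools were STAR, RSEM, Bowtie2 and DESeq2 and the genome build was hg19. Which tool made which table, the tool versions, the gene annotation and the use of strand in counting are not given in the sources used here. Because strand use is not stated, reads of overlapping and antisense genes cannot be assigned with certainty. No genome positions are printed, because the annotation used here (GENCODE 29, on GRCh38) is of another build than the tables. It served only for gene types, transcript lengths and GC content, matched by Ensembl identifier (99.3% of the 19792 identifiers of the MDA-MB-231 table and 97.7% of the 33586 of the MCF7 table).

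The MDA-MB-231 table, per the file headers, holds raw read counts per gene for 4 libraries, which the authors also deposited as normalized counts. These normalized signal values are counts that the authors divided by 1 size factor per library, as deposited, with factors between 0.933 and 1.05 as found from the values. The same table holds the authors' log2 fold changes with their p-values and adjusted p-values. The MCF7 table, per the file headers, holds 1 RSEM column for each of 6 groups, taken here as TPM (each gene's length-corrected share of all transcripts) from the values. In these deposited TPM columns every value is a multiple of 0.005 (after rounding to 4 decimals of that step), as means of 2 values with 2 decimals are. The columns sum to between 942371.8 and 956246.8 TPM, so part of the total lies outside the genes of 5 types that the table lists. Values per library and read depth are not analysed here, so MCF7 values carry no SD, n or p. The authors also deposited log-scaled values for expression and localization in MCF7. Their base and scaling are not given in the sources used here. Judged from the values, the localization columns are cytosol over nucleus. Across genes the authors' columns followed the TPM ratios with slopes of 0.66 for whole-cell expression, 0.92 for siCtrl localization and 0.89 for the change of localization, and they are used here only for NUP93.

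Samples were grouped by cell line, fraction and siRNA as the labels give them, with 2 libraries in each of 8 groups. The labels call them biological replicates and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The MDA-MB-231 libraries are numbered 2 and 3 in each treatment. Between the libraries of a treatment, chi-square per degree of freedom over genes with a mean of at least 50 counts was 1.84 for siCtrl and 1.20 for siNUP93, where counting noise alone gives 1. The fitted common dispersion corresponds to a coefficient of variation of 1.26%.

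For MDA-MB-231, edgeR 4.0.16 in R 4.3.3 was run on the raw counts with filterByExpr (15554 genes kept), TMM scaling and the quasi-likelihood test (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values use the TMM library sizes. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 30 lists, and again with an estimated correlation and with fry. The form with an estimated correlation rests on the few residual degrees of freedom of 4 libraries, which by itself raises its p-values. On simulated counts with the real means, library sizes and dispersions of this comparison (15338 genes tested), the test called 46 of 68 genes changed by 0.25 on the log2 scale, 42 of 64 changed by 0.5 and 61 of 65 changed by 1. It also called 8 of 15141 unchanged genes, which made up 5.1% of its calls. Only 200 genes were changed in the simulation, far fewer than were called in the data. The share of unchanged genes called there thus does not carry over to the data.

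For MCF7 the planned test needs values per library and the table holds group means in TPM, so it was not run and each comparison is a description. Several choices for MCF7 were made after the data were examined: centring on the median gene as the leading scaling in place of TMM (centring and values as deposited had both been listed as replacements), the minimum of 10 TPM, the 2-fold rule, the percentile limits, and ranking list members by the size of the ratio. The log2 ratio of TPM + 1 was taken for genes with a mean of at least 10 TPM over the columns compared, and the median ratio of those genes was subtracted. A ratio on this scale understates the change of low genes. Genes at least 2-fold from the median gene were counted. A list with at least 5 such members was described by the percentile of its median among 10000 random lists of its size matched on mean expression in 20 bins, and was said to stand apart at or below percentile 0.1 or at or above 99.9. Lists that stood apart in the cytosol, the nucleus or the change of their ratio were also set against random lists matched on the siCtrl nuclear-to-cytosolic ratio, a choice made after the data were examined, since these comparisons share siCtrl values with that ratio. The 2-fold rule was also run on simulated columns (7057 genes in the whole-cell step). It returned 88 of 88 genes changed by 1.5 and 89 of 89 changed by 2.5 on the log2 scale, and none of 6850 unchanged genes. The noise of each simulated column was set by hand at an SD of 0.1 on the log2 scale, since no replicate spread is known. The real whole-cell ratios had an SD of 0.39 across genes. The simulation therefore checks the calculation and does not give the rate of false 2-fold genes.

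The lists and the rule for named genes were fixed before the data were examined. NUP93 is given throughout. For each comparison the rule takes the 6 largest rises and 6 largest falls past the threshold with a mean of at least 10 CPM or TPM, the same direction in every replicate and a symbol that is not a clone, locus or pseudogene name. It adds the 4 members with the smallest p of each list with at least 3 members past the threshold, and at most 2 of other lists. Without p-values in MCF7, list members were ranked there by the size of the ratio, 4 for lists that stood apart and 2 for others. Some are left out for length. Genes that share reads with near-identical or overlapping genes are named as uncertain.

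Alternatives tried for MDA-MB-231 were RLE size factors, library size alone, no filter beyond 1 read, DESeq2 1.42.0, the replicate number as a block, an absolute log2 fold change of at least 1, and each library left out. For MCF7 they were values as deposited without centring, no filter, and a pseudocount of 0.1. Leaving out the mitochondrially encoded genes, a minimum of 30 TPM and an absolute log2 fold change of at least 0.5 were added after seeing the data. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.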

Results

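Poly(A) RNA was sequenced from 2 breast cancer cell lines after knockdown of NUP93, a scaffold nucleoporin of the inner ring of the nuclear pore complex. MDA-MB-231 is a triple-negative line with mesenchymal features, and MCF7 is an estrogen receptor-positive line with luminal features. Whole-cell RNA of MDA-MB-231 was profiled in 2 siCtrl and 2 siNUP93 libraries. Whole-cell, cytosolic and nuclear RNA of MCF7 was profiled in 12 libraries, 2 for each fraction and siRNA. The MDA-MB-231 libraries held 29039867 and 29392979 counts under siCtrl and 26208846 and 27756948 counts under siNUP93. Their table lists 19792 genes, of which 458 had no count. The MCF7 values are the authors' mean TPM for each fraction and siRNA, with no values per library, so no MCF7 difference has a replicate check, and its read depth is unknown.

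The targeted transcript was lower in both siNUP93 libraries of MDA-MB-231 and in the siNUP93 mean of each MCF7 fraction. In MDA-MB-231, NUP93 (ENSG00000102900) was at 109.5 and 111.7 CPM in the siCtrl libraries and at 15.4 and 16.5 CPM in the siNUP93 libraries, or 110.6 ± 1.58 against 15.9 ± 0.77 CPM (SD, n = 2). This was 6.94-fold lower (log2 fold change -2.79 ± 0.05 SE, edgeR adjusted p = 6.33e-37). In MCF7, NUP93 went from 49.3 to 19.2 TPM in whole-cell extracts, from 42.4 to 5.26 TPM in the cytosol and from 55.3 to 33.1 TPM in the nucleus. The authors' deposited table gives a NUP93 log2 fold change of -2.79 in MDA-MB-231, and for MCF7 a whole-cell change of -0.87 and a change of -2.28 in the cytosolic-over-nuclear localization, on log-scaled columns whose scaling is not given.

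**Figure D1:**
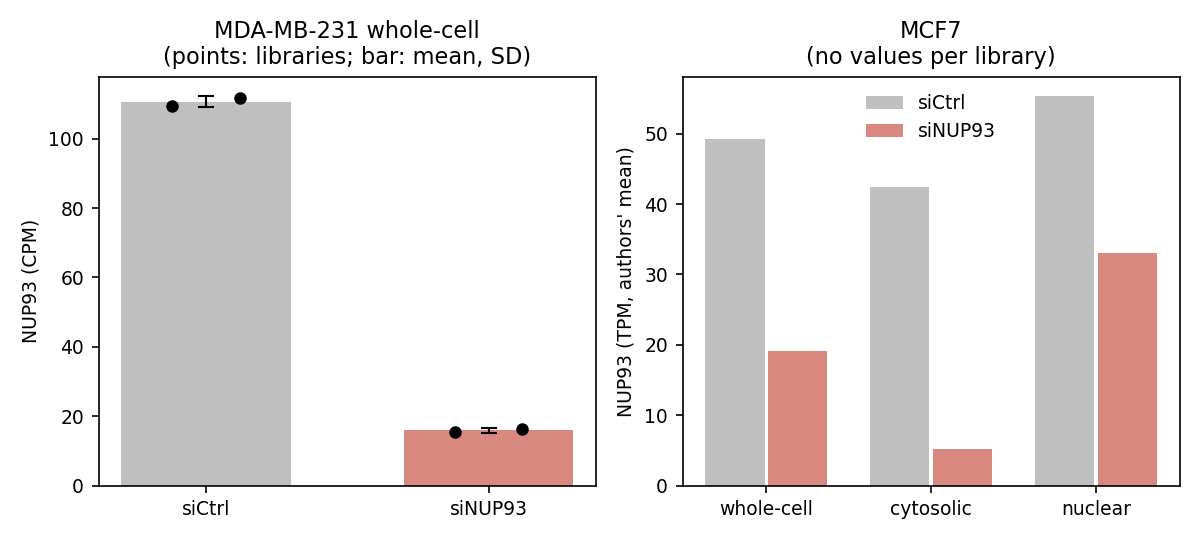
NUP93 transcript level by siRNA. Left, CPM in the MDA-MB-231 libraries (points), with the mean (bar) and SD (error bar) of 2 libraries per group, 110.6 CPM under siCtrl and 15.9 CPM under siNUP93. Right, the authors' mean TPM in the 3 MCF7 fractions, which has no error bar because values per library were not used, and which is lowest, at 5.26 TPM, in the siNUP93 cytosol.

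The first comparison asked how the MDA-MB-231 transcriptome differs after NUP93 knockdown. All 13 mitochondrially encoded mRNAs fell, while most ribosomal protein mRNAs and many EGF/ERK-induced and feedback, YAP/TEAD and sterol genes rose by smaller amounts. MT-CO1, a subunit of cytochrome c oxidase, fell 2.22-fold from 3865 ± 302 to 1742 ± 25.8 CPM (SD, n = 2, log2 fold change -1.15 ± 0.03 SE, edgeR adjusted p = 3.07e-32). MT-CO3 fell 2.21-fold and MT-ATP6 fell 2.16-fold. The other members of the 6 largest falls were NUP93, ESM1, an endothelial-type secreted proteoglycan (2.62-fold, from 42.6 to 16.2 CPM), and SNHG19, a noncoding snoRNA host gene (2.34-fold, from 22.2 to 9.50 CPM). The 6 largest rises were GDF15, a stress-induced cytokine of the TGF-beta family (2.27-fold, from 7.89 to 17.9 CPM), TGFB2, a TGF-beta ligand (2.27-fold, from 41.2 to 93.6 CPM), ARRDC3, an alpha-arrestin (2.14-fold), SLC44A2, a choline transporter-like protein (2.14-fold), KRT80, a keratin (1.97-fold), and AQP3, an aquaporin (1.91-fold). Each of these 12 genes had an edgeR adjusted p of 1.29e-13 or less, and in each both siNUP93 libraries lay on the same side of both siCtrl libraries.

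Of the 15554 genes tested, 2998 rose and 2724 fell at an adjusted p of 0.05, 36.8% of all genes tested. Most changes were small: the median absolute log2 fold change of the called genes was 0.20, and 81 rose and 137 fell by at least 2-fold. DESeq2 called 2887 genes in place of 5722, 2886 of them in the same direction as edgeR, and 12 rose and 25 fell by at least 2-fold in DESeq2. The authors' deposited table has 1511 higher and 1096 lower genes at its adjusted p of 0.05, and every one of these 2607 was also called here in the same direction. The fitted coefficient of variation between replicates was 1.26%, so small differences passed the test.

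The mitochondrially encoded mRNAs had a median log2 fold change of -1.05, and all 13 fell, over all genes and adjusted over the list alone (camera adjusted p = 1.94e-10; with an estimated correlation the adjusted p was 0.368). MT-ND5 fell 1.90-fold and MT-ATP8 fell 2.13-fold. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 had log2 fold changes of -0.95 and -0.84. Mitochondrial genes took 3.51% and 3.19% of the counts of the siCtrl libraries and 1.66% and 1.67% of those of the siNUP93 libraries. Reads of these genes can also match nuclear copies, which fell with them. In contrast to the mitochondrial mRNAs, 38 of 66 nuclear-encoded oxidative phosphorylation genes rose and 3 fell (42 and 3 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 2.4e-05; adjusted p = 0.209 with an estimated correlation). ATP5B, the catalytic beta subunit of ATP synthase, rose 1.16-fold, while NDUFA6, a complex I subunit, fell 1.27-fold. Of 77 cytosolic ribosomal protein genes, 60 rose and 2 fell (61 and 2 adjusted over the list alone), with a median log2 fold change of 0.11 (camera adjusted p = 3.6e-09; adjusted p = 0.209 with an estimated correlation). RPL12 rose 1.28-fold and RPL37A rose 1.15-fold, and both have pseudogenes that can share their reads.

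Genes induced by growth factor, YAP/TEAD and TGF-beta signalling moved up. Of 30 EGF/ERK-induced and feedback genes, 20 rose and 5 fell (21 and 5 adjusted over the list alone; camera adjusted p = 0.000154; adjusted p = 0.209 with an estimated correlation). DUSP1, a MAP kinase phosphatase, rose 1.75-fold, EREG, an EGF receptor ligand, rose 1.68-fold and MYC rose 1.44-fold, while MCL1, an anti-apoptotic BCL2 family member, fell 1.43-fold. Of 20 YAP/TEAD targets, 14 rose and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 0.000119, and adjusted p = 0.209 with an estimated correlation), among them CYR61, a matricellular protein (1.63-fold), F3, the tissue factor (1.45-fold), and ANKRD1 (1.39-fold). Of 27 TGF-beta/SMAD targets, 16 rose and 3 fell (17 and 4 adjusted over the list alone; camera adjusted p = 0.000285, and adjusted p = 0.209 with an estimated correlation), led by the inhibitors of differentiation ID1 (1.81-fold) and ID3 (1.56-fold).

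Sterol, secretory and stress genes also rose on balance. Of 33 cholesterol synthesis and SREBP target genes, 22 rose and 2 fell (23 and 2 adjusted over the list alone; camera adjusted p = 1.45e-05, and adjusted p = 0.209 with an estimated correlation). INSIG1, a sterol-responsive regulator of SREBP processing, rose 1.48-fold and LDLR, the LDL receptor, rose 1.29-fold. Of 32 hypoxia and glycolysis genes, 19 rose and 2 fell (20 and 3 adjusted over the list alone; camera adjusted p = 0.000219, and adjusted p = 0.304 with an estimated correlation). Of 39 endoplasmic reticulum and secreted protein genes, 23 rose and 3 fell (23 and 3 adjusted over the list alone; camera adjusted p = 0.000235, and adjusted p = 0.209 with an estimated correlation). Of 35 unfolded protein and integrated stress response genes, 18 rose and 4 fell (20 and 4 adjusted over the list alone; camera adjusted p = 0.00247, and adjusted p = 0.228 with an estimated correlation). HSPA5, the chaperone BiP, rose 1.16-fold. Of 22 NF-kappaB and inflammatory genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone), with IER3 at 1.42-fold and CXCL8 at 1.35-fold. Its camera adjusted p of 0.011 became 0.368 with an estimated correlation and 0.0826 without siCtrl replicate 3.

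Genes of G1/S and DNA replication, MYC targets and nuclear-retained noncoding RNAs fell on balance. Of 45 genes of G1/S and DNA replication, 23 fell and 5 rose (23 and 6 adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.304 with an estimated correlation), with MCM5, a subunit of the replicative helicase, 1.26-fold lower. Of 40 MYC targets, 17 fell and 4 rose over all genes and over the list alone (camera adjusted p = 0.0154, 0.285 with an estimated correlation and 0.0712 without siNUP93 replicate 2), although MYC itself rose. TFRC, the transferrin receptor, fell 1.55-fold. Of 20 nuclear-retained noncoding RNAs, 11 fell and 4 rose (12 and 4 adjusted over the list alone; camera adjusted p = 0.0188; adjusted p = 0.368 with an estimated correlation). LINC00657 (NORAD) fell 1.98-fold, NEAT1, the scaffold RNA of paraspeckles, fell 1.46-fold and MALAT1, a nuclear speckle RNA, fell 1.38-fold. In the MCF7 control fractions NORAD was not nuclear-rich, at 30.1 TPM in the nucleus and 32.6 TPM in the cytosol. The camera adjusted p of this list was 0.0506 without siCtrl replicate 3 and 0.0712 without siNUP93 replicate 2.

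The remaining 16 lists did not pass camera's threshold. Among 29 nucleoporins other than NUP93, 6 rose and 6 fell over all genes and over the list alone (camera adjusted p = 0.624), with RANBP2, a cytoplasmic filament nucleoporin, 1.18-fold lower. Among 30 importins, exportins and Ran cycle genes, 11 rose and 4 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.141), with TNPO2, a transportin, 1.38-fold higher and XPO1, the main protein exportin, 1.16-fold higher. Among 22 mRNA export factors, 7 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.595). The adaptor ALYREF rose 1.45-fold and the export receptor NXF1 rose 1.33-fold, while the helicase DDX39B fell 1.45-fold. Of 22 mesenchymal and basal markers, 10 rose and 5 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.142), and of 19 luminal markers, 7 rose and 1 fell (8 and 1; camera adjusted p = 0.175). TGFBI, a secreted matrix protein, rose 1.56-fold and AGR2, a protein disulfide isomerase of luminal cells, rose 1.59-fold. Of 45 G2/M genes, 19 rose and 11 fell (20 and 11; camera adjusted p = 0.333), with the proliferation marker MKI67 1.33-fold lower, and of 34 interferon-stimulated genes, 13 rose and 5 fell (13 and 5; camera adjusted p = 0.133), with IFIT2 1.51-fold higher. Of 28 p53 targets, 12 rose and 7 fell (13 and 8; camera adjusted p = 0.15, upward, with a median log2 fold change of 0.14), while fry gave the opposite direction (adjusted p = 0.00417, downward, limma). CDKN1A, the cell cycle inhibitor p21, fell 1.56-fold and PLK2, a polo-like kinase, rose 1.16-fold. Among markers of other cell types, 2 of 5 immune and blood cell genes rose and none fell, and 1 of 7 fibroblast and endothelial genes rose and none fell, with the same counts adjusted over the list alone. CD14 and PECAM1 among these, both under 2 CPM, lost their edgeR calls without siCtrl replicate 2.

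In MCF7 whole-cell extracts, VIM, the intermediate filament vimentin, was at 35.5 TPM under siCtrl and 181 TPM under siNUP93, and SPARC, a matrix glycoprotein, at 19.5 and 94.0 TPM. HOXC6, a homeobox gene, went from 1.27 to 21.5 TPM and CELF3, an RNA-binding protein, from 3.08 to 24.8 TPM. The fractions did not follow these increases throughout. In the cytosol VIM went from 58.5 to 72.2 TPM, SPARC from 29.98 to 29.6 TPM, HOXC6 from 8.16 to 2.85 TPM and CELF3 from 7.76 to 8.78 TPM. In the nucleus VIM went from 87.3 to 127 TPM, SPARC from 50.1 to 49.98 TPM, HOXC6 from 7.54 to 6.44 TPM and CELF3 from 16.1 to 10.7 TPM. For each of these genes the whole-cell value lay below both fractions under siCtrl and above both under siNUP93. A mixture of cytosol and nucleus would lie between them, so these whole-cell increases are uncertain. The mesenchymal and basal markers, 2 of 8 at least 2-fold higher, and the integrin and extracellular matrix genes, 1 of 14, had medians within matched random lists (percentiles 87.7 and 94.7). Among the largest decreases were DPM3, a subunit of dolichol-phosphate mannose synthase (149 to 55.4 TPM), CBS, cystathionine beta-synthase (51.0 to 17.3 TPM), and FBXO9, an F-box protein (23.7 to 8.46 TPM). FBXO9 went the other way in the cytosol, from 14.96 to 28.2 TPM, and from 39.7 to 22.6 TPM in the nucleus, while CBS was lower in both, at 18.0 and 11.4 TPM in the cytosol and 136 and 82.1 TPM in the nucleus. The read-through gene NDUFC2-KCTD14 and LUZP6, which overlap other genes and share their reads, had larger apparent decreases and are uncertain. Of 7274 genes compared, 109 were at least 2-fold higher and 42 at least 2-fold lower than the median gene. With a minimum of 30 TPM, a choice made after seeing the data, 18 were higher and 12 lower, so most of these differences lay in weakly expressed genes.

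Among the lists, 2 stood apart in MCF7 whole-cell extracts. The 15 nuclear-retained noncoding RNAs had a median log2 ratio of 0.30 (percentile 99.91, and 99.85 with a pseudocount of 0.1, just within the limit), with RMRP at 33.1 TPM under siCtrl and 92.5 TPM under siNUP93 and MALAT1 at 426 and 626 TPM, whereas NORAD was lower (log2 ratio -0.78). MALAT1 was thus higher in MCF7 and lower in MDA-MB-231 under siNUP93, a difference between the lines that was not tested. RMRP has no poly(A) tail, so its values in these poly(A) libraries are uncertain. The 77 ribosomal protein mRNAs had a median of 0.07, above every matched random list, and none of them was 2-fold from the median gene. The 12 mitochondrially encoded mRNAs above the minimum had a median log2 ratio of -0.09 (percentile 19.3) and ranged from -0.64 for MT-ND5 to 0.30. MT-ND6, under the minimum, went from 3.97 to 1.27 TPM (log2 ratio -1.15). Of 25 hypoxia and glycolysis genes 4 were at least 2-fold higher, among them ERO1A and NDRG1 (log2 ratios of 1.71 and 1.30), at percentile 98.96 of the list's median.

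**Figure D2:**
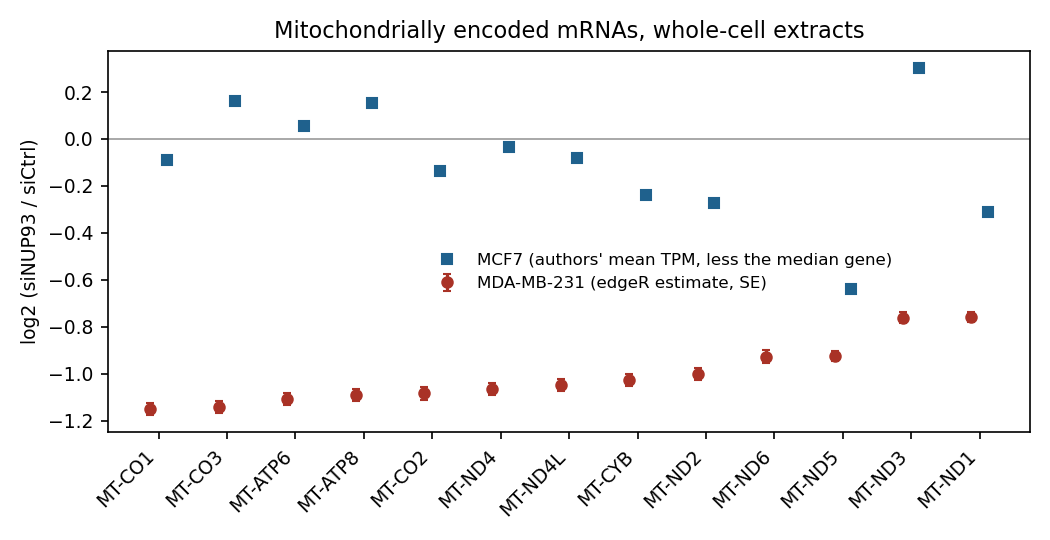
Change of each mitochondrially encoded mRNA in whole-cell extracts, as log2 of siNUP93 over siCtrl. Circles are edgeR estimates in MDA-MB-231 with SE (2 libraries per group), which lie between -1.15 and -0.76. Squares are ratios of the authors' mean TPM in MCF7 relative to the median gene, without error, for the 12 mRNAs above the minimum of 10 TPM, which lie between -0.64 and 0.30 (MT-ND6, at -1.15, is left out).

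In the MCF7 cytosol, the RNAs with the largest decreases included the knockdown target and SNHG19. SNHG19 went from 32.6 to 1.68 TPM, NUP93 from 42.4 to 5.26 TPM, LOXL1, a lysyl oxidase, from 20.6 to 4.58 TPM, AKAP13, a Rho guanine nucleotide exchange factor, from 17.2 to 4.79 TPM, and DPM3 from 191 to 65.0 TPM. Nuclear levels of the same RNAs were closer to control: SNHG19 went from 39.9 to 28.8 TPM, LOXL1 from 14.1 to 13.0 TPM and DPM3 from 76.0 to 67.9 TPM. The cytosolic increases included PCF11, a transcription termination factor (4.24 to 19.5 TPM), AFF4, a scaffold of the super elongation complex (15.1 to 55.1 TPM), and KLHL7 (11.3 to 40.7 TPM). NDUFC2-KCTD14, BLOC1S5-TXNDC5, NOMO3 and POLR2J2 also met the rule and are uncertain, since near-identical or overlapping genes share their reads. Of 6512 genes, 93 were at least 2-fold higher and 82 lower relative to the median gene, whose own log2 ratio was 0.12. Without that centring the counts were 166 and 49, and with a minimum of 30 TPM 46 and 33.

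Cytosolic mRNAs of the ribosome and of the respiratory chain were lower and TGF-beta/SMAD targets higher. The 77 ribosomal protein mRNAs had a median log2 ratio of -0.36 (percentile 0.02) and the 66 nuclear-encoded oxidative phosphorylation mRNAs a median of -0.35 (percentile 0.01). RPS29 and ATP5E, an ATP synthase subunit, had ratios of -1.15 each, while RPL15 went the other way (1.08). Among 15 TGF-beta/SMAD targets the median was 0.57 (percentile 99.99, and 99.67 without a filter on low values, within the limit), with THBS1, the matricellular protein thrombospondin 1, at 1.42 and ID2 at 0.97. The 40 endoplasmic reticulum and secreted protein mRNAs had a median of 0.14 (percentile 99.92), including EPCAM at 0.82 and HSP90B1 at -0.74. Relative to values as deposited, the ribosomal and respiratory chain medians kept their sign. Against random lists matched on the nuclear-to-cytosolic ratio under siCtrl, which shares its siCtrl cytosolic values with these changes, the ribosomal protein mRNAs (random median -0.28, percentile 7.81) and the endoplasmic reticulum list (percentile 96.2) lay within the limits. The oxidative phosphorylation mRNAs (percentile 0.1) and the TGF-beta/SMAD targets, above every such list, still stood apart. Whole-cell extracts did not show the same shifts. There the ribosomal protein mRNAs had a median of 0.07, in the opposite direction, and the oxidative phosphorylation mRNAs one of -0.06 (percentile 24.2). The TGF-beta/SMAD targets lay within the limits in whole-cell extracts (median 0.13, percentile 86.3) and in the nucleus (0.08, percentile 79.4).

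In the MCF7 nucleus, p53 targets and ribosomal protein and oxidative phosphorylation mRNAs lay above random lists matched on expression. The 24 p53 targets had a median log2 ratio of 0.30 (percentile 99.96, and 96.42 for the 10 members with a minimum of 30 TPM, within the limit), with BBC3, the pro-apoptotic protein PUMA, at 1.02, MDM2, the p53 ubiquitin ligase, at 0.96, BTG2 at 0.88 and TIGAR at -1.54. The ribosomal protein mRNAs had a median of 0.23 and the oxidative phosphorylation mRNAs a median of 0.21 (percentile 99.99), the ribosomal median lying above every random list. Against random lists matched on the siCtrl nuclear-to-cytosolic ratio, the ribosomal and oxidative phosphorylation mRNAs did not stand apart (percentiles 3.14 and 50.6), and the p53 targets lay above every list. The largest increases were IFI30, a lysosomal thiol reductase (3.63 to 29.6 TPM), PRRT2 (5.49 to 29.2 TPM) and CRIP1 (8.43 to 42.1 TPM). The largest decreases were RASGRP3 (22.9 to 3.12 TPM), PLCB1, a phospholipase C (103 to 19.4 TPM), and ZNF236 (24.4 to 4.54 TPM). HIST1H2BO, TMEM191C, TMEM191B and FKSG63 have near-identical copies and are uncertain. Of 8562 genes, 93 were at least 2-fold higher and 86 lower relative to the median gene. As deposited, 56 were higher and 114 lower, and with a minimum of 30 TPM 20 and 18.

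The control fractions show what each fraction held. Under siCtrl the median gene had a nuclear-to-cytosolic log2 ratio of 0.63, and relative to it 1388 of 7802 genes were at least 2-fold nuclear and 1061 at least 2-fold cytosolic. Without centring the counts were 2793 and 205. MALAT1 was at 2789 TPM in the nucleus and 242 TPM in the cytosol, and NEAT1 at 290 and 32.4 TPM. The 17 nuclear-retained noncoding RNAs had a median of 1.08 above the median gene (percentile 99.99), but they did not all match the list's name. Relative to the median gene 9 were at least 2-fold nuclear and 3 at least 2-fold cytosolic. These 3, named after their values were seen, were RPPH1 (30.4 TPM in the cytosol and 14.1 TPM in the nucleus), DANCR (46.0 and 32.1 TPM) and ZFAS1 (114.9 and 84.3 TPM). RPPH1 has no poly(A) tail, so its values in these poly(A) libraries are uncertain and need not reflect its location. Ribosomal protein mRNAs (median -1.498) and oxidative phosphorylation mRNAs (median -1.17) lay on the cytosolic side, below every matched random list. The 13 mitochondrially encoded mRNAs lay within matched random lists (median -1.11, percentile 32.0), with 8 at least 2-fold cytosolic and 1 at least 2-fold nuclear. MT-ND3, the most cytosolic of them, was at 3226 TPM in the cytosol and 823 TPM in the nucleus, MT-ND5 at 2314 and 4159 TPM, and MT-ND6 at 6.31 and 35.8 TPM. The most nuclear genes by the rule included ITGB3BP, a centromere protein, at 281 TPM in the nucleus and 4.53 TPM in the cytosol and CSAD, an enzyme of taurine synthesis, at 193 and 3.08 TPM. The others were NPIPB2, NPIPB4, NPIPB5 and FKSG61, which share reads with near-identical copies and are uncertain, as is POLR2J2 on the cytosolic side. SCO2, a cytochrome c oxidase assembly factor, was at 41.2 TPM in the cytosol and 7.05 TPM in the nucleus.

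The last MCF7 comparison asked whether the nuclear-to-cytosolic ratio of an RNA differed between siNUP93 and siCtrl. Ribosomal protein and oxidative phosphorylation mRNAs, cytosolic under siCtrl, had higher ratios by medians of 0.66 and 0.65 relative to the median gene, whose ratio changed by -0.22, and both lay above every random list matched on expression. The change shares its siCtrl values with the siCtrl ratio, and over 7650 genes, which are not independent replicates, the Pearson r between them was -0.49. Random lists as cytosolic under siCtrl had median changes of 0.62 and 0.43, which put the ribosomal protein mRNAs at percentile 72.8 and the oxidative phosphorylation mRNAs at 99.94. Ribosomal protein mRNAs thus did not stand apart from equally cytosolic RNAs, and oxidative phosphorylation mRNAs did. RPS26 and NDUFA13, a complex I subunit, had changes of 1.74 and 1.71, and 16 of 77 and 15 of 66 members changed by at least 2-fold upward and none downward. Their medians were also below the median gene in the cytosol and above it in the nucleus. SNHG19 (3.40) and NUP93 (2.28) had high changes too, through their cytosolic decrease. GPN2, a GTPase, went from 41.6 to 21.9 TPM in the cytosol and from 18.0 to 44.8 TPM in the nucleus. The ratio was lower for ZFC3H1 (2.58 to 13.5 TPM in the cytosol and 48.8 to 24.1 TPM in the nucleus). It was also lower for KLHL7 and for IL6ST, the shared receptor of interleukin 6 family cytokines (9.34 to 14.4 TPM and 29.99 to 7.48 TPM).

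Of 7766 genes compared, 358 had a ratio at least 2-fold higher and 330 a ratio at least 2-fold lower than the median gene. Without centring the counts were 180 and 590, and with a minimum of 30 TPM 158 and 149. Nucleoporins, importins and exportins, and mRNA export factors lay within matched random lists (percentiles 6.97, 1.09 and 63.7), and so did the nuclear-retained noncoding RNAs (median 0.06, percentile 60.4). Across 7650 genes, which are not independent replicates, the cytosolic and nuclear changes had a Pearson r of -0.01, and each had an r of 0.19 and 0.12 with the whole-cell change.

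**Figure D3:**
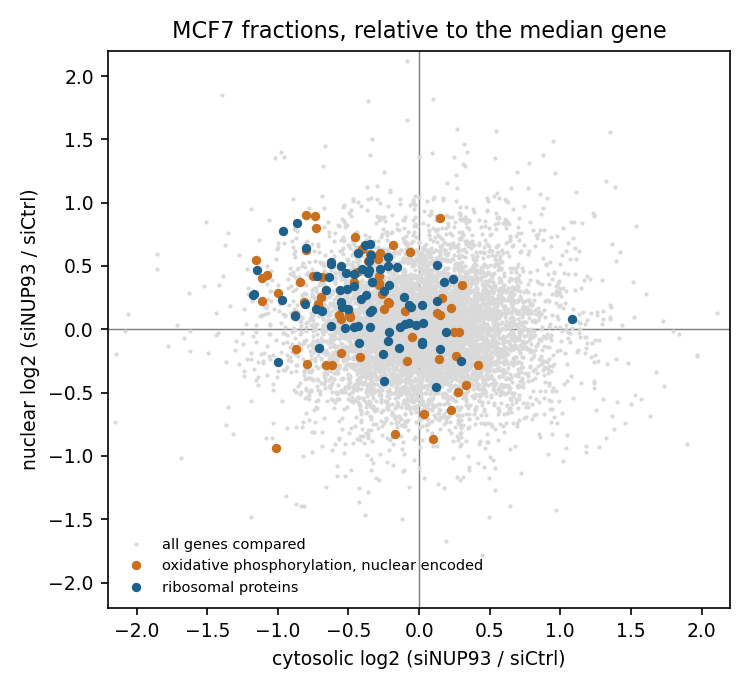
Change of each transcript in the MCF7 cytosol (horizontal axis) and nucleus (vertical axis), as log2 of siNUP93 over siCtrl from the authors' mean TPM and relative to the median gene, without error. Grey points are 7754 genes with a mean of at least 10 TPM, and 12 genes lie outside the axes. Ribosomal protein (blue) and nuclear-encoded oxidative phosphorylation genes (orange) lie in the upper left for 56 of 77 and 40 of 66 members, with cytosolic medians of -0.36 and -0.35 and nuclear medians of 0.23 and 0.21.

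The whole-cell responses of both lines were set side by side over 6904 genes, with each table normalized on its own. Decreases were shared more often than independent lists would give at the minimum of 10 TPM, and not without it. Of 1376 genes that fell in MDA-MB-231 and 28 at least 2-fold lower in MCF7, 16 were in common, where 5.58 would be by chance (Fisher's exact test, two-sided, p = 1.51e-05, across genes that are not independent). Without a filter on low values in MCF7, 44 decreases were in common against 37.9 by chance (p = 0.277, Fisher's exact test). The 16 include NUP93, DPM3 (log2 fold change -0.94 in MDA-MB-231) and LOXL1 (-0.71), and also TOMM7, a mitochondrial import subunit (-0.80), and UBE2S, a ubiquitin-conjugating enzyme (-0.29), both chosen after their values were seen. Increases were shared by 16 genes against 26.4 by chance (p = 0.0146, Fisher's exact test), a shortfall that was lost under several alternatives. The Fisher p was 0.228 without siCtrl replicate 2, 0.0859 without siCtrl replicate 3, 0.26 without siNUP93 replicate 2 and 0.108 without siNUP93 replicate 3. It was 0.0617 with a pseudocount of 0.1 in MCF7, and with DESeq2 calls in MDA-MB-231 there were 13 shared increases against 15.02 by chance (p = 0.668, Fisher's exact test). A further 14 genes that fell in MDA-MB-231 were at least 2-fold higher in MCF7, where 18.3 would be by chance (p = 0.294, Fisher's exact test). Without siCtrl replicate 3 there were 7 such genes against 16.4 by chance (p = 0.00851), without a filter in MCF7 59 against 77.3 (p = 0.0179), and with DESeq2 calls 5 against 9.38 (p = 0.161, Fisher's exact test). None that rose by edgeR was at least 2-fold lower in MCF7, where 8.05 would be by chance (p = 9.35e-05, Fisher's exact test). There were also 0 at an unadjusted edgeR p of 0.05 and 0 with DESeq2 calls, 1 without siCtrl replicate 2 (7.68 by chance) and 1 without siNUP93 replicate 2 (6.76 by chance). Without a filter in MCF7 there were 18 against 44.2 by chance (p = 1.28e-06, Fisher's exact test). The chance counts take no account of expression level, and most 2-fold genes in MCF7 were weakly expressed. Genes that rose in MDA-MB-231 were short among MCF7 2-fold genes of both directions. These shortfalls therefore do not show that the lines avoid opposite changes. Of all MDA-MB-231 calls 59.2% had the same sign in MCF7, where the margins give 50.3%. Pearson's r across genes was 0.16 over all genes and 0.23 over the MDA-MB-231 calls.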

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

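Leaving out the mitochondrially encoded genes, the minimum of 30 TPM and the absolute log2 fold change of 0.5 were tried only after the data were seen, and the other alternatives were planned. In MDA-MB-231 the 5722 called genes became 5714 with RLE size factors, 5668 with library size alone, 5410 without a filter, 5735 without mitochondrial genes and 4388 to 5038 with each library left out, where the lone library is assumed to vary like the others. DESeq2 called 2887, with 7122 adjusted p-values given as NA, and the added requirement of an absolute log2 fold change of 1 left 218 in edgeR (37 in DESeq2), the latter by its own construction and the former for a cause that was not tested. Of the 14 lists past camera's threshold, 0 were left with an estimated correlation (7 had an unadjusted p under 0.05 in limma's camera), and 22 passed fry, which does not compare a list with other genes. With the few residual degrees of freedom of 4 libraries, this loss does not show that gene correlation undid the calls. The EGF/ERK list had an estimated correlation of -0.0119, below the preset 0.01, and its unadjusted camera p still went from 3.08e-05 to 0.0419. Other lists had higher estimates, up to 0.96 for the mitochondrially encoded mRNAs. With each library left out 12 to 14 passed. The p53 targets moved up in camera without passing and down in fry (adjusted p = 0.00417). With the replicate number as a block, MDA-MB-231 gave 5985 genes, 15 lists and 33 shared genes. Deviations of libraries with the same number had a correlation of 0.01, which gives no sign of pairing. It cannot exclude pairing, because the libraries of a treatment differed by little more than counting noise.

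Without a filter the MCF7 counts of 2-fold genes became 1162 in whole-cell extracts, 945 in the cytosol, 1694 in the nucleus, 4873 for nucleus against cytosol and 2945 for the change of that ratio, because more genes enter. With a minimum of 30 TPM they became 30, 79, 38, 1347 and 307, because fewer do. As deposited without centring and with a pseudocount of 0.1 each total stayed within 1.5 times its value, while the split of higher against lower genes moved as the report gives it. The 32 genes with the same direction in both lines became 114 without a filter in MCF7, where the shared decreases no longer exceeded chance (44 against 37.9, Fisher's exact test p = 0.277), and 7 with an absolute log2 fold change of 0.5 in MDA-MB-231, and 27 to 31 with each MDA-MB-231 library left out. The 14 MCF7 list medians that stood apart kept their sign as deposited, without a filter, with a pseudocount of 0.1 and with a minimum of 30 TPM. Their percentiles, recomputed after the data were seen, stayed outside the limits for 13 of 14 lists under each of the last 3 settings. The exceptions were TGF-beta/SMAD targets in the cytosol without a filter (99.67), nuclear-retained noncoding RNAs in whole-cell extracts with a pseudocount of 0.1 (99.85) and p53 targets in the nucleus with a minimum of 30 TPM (96.42), and the cause was not tested. Centring shifts a list and its random lists alike, so values as deposited do not test the percentiles. Random lists matched on the siCtrl ratio, a choice made after the data were seen, left 4 of the 9 fraction lists outside the limits, as the report gives them. No paired analysis was possible in MCF7 because its columns carry no replicate, and for the same reason RLE size factors, DESeq2, the block across or within treatments, leaving out libraries and fitting only the libraries compared were not run there. Among the named genes, CD14 lost its edgeR call without siCtrl replicate 2 or either siNUP93 library and PECAM1 without siCtrl replicate 2, both at under 2 CPM. No called value of a named gene changed sign under the alternatives run for it. The read depth of MCF7 is unknown, so its counting error cannot be had from TPM.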

Other observations

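The tests of the mitochondrial pattern and of RNA carried over between fractions were chosen after the results were seen, and those of GC content and of the shared siRNA effect were written before theirs. Beyond the named genes, ACTA2, smooth muscle actin, and FSTL1, a secreted glycoprotein, moved with VIM and SPARC in MCF7 whole-cell extracts, from 15.4 to 56.4 TPM and from 9.20 to 36.1 TPM. Both were chosen after their values were seen. In the nucleus they went from 27.1 to 43.9 TPM and from 11.8 to 34.7 TPM, and in the cytosol from 26.7 to 25.5 TPM and from 10.8 to 17.7 TPM. As for VIM and SPARC, their whole-cell values lay below both fractions under siCtrl and above both under siNUP93. Their whole-cell increases are equally uncertain. The fibrillar collagens COL1A1 and COL3A1, the fibroblast markers above the minimum, had whole-cell log2 ratios of -0.13 and 0.10. The median of the 8 mesenchymal and basal markers was at percentile 87.7. In MDA-MB-231 the log2 fold change was -0.10 for VIM, -0.64 for ACTA2 and 0.32 for FSTL1, each past the edgeR threshold.

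The first pattern is the fall of mitochondrially encoded RNAs in MDA-MB-231. A shift of reads to nuclear copies of the mitochondrial genome would raise those copies, but the summed CPM of 8 of them changed by -353. A lower expression of the respiratory chain as a whole would lower its nuclear-encoded genes, whose median log2 fold change was 0.0849. A response common to both lines would lower the same mRNAs in MCF7 whole-cell extracts, where the median of the 12 above 10 TPM was -0.0865, each above those of MDA-MB-231, and that of all 13 was -0.09 with MT-ND6, at 3.97 and 1.27 TPM (log2 ratio -1.15). NUP93 itself fell less in MCF7 whole-cell extracts (2.49-fold) than in MDA-MB-231 (6.94-fold), and the MCF7 values have no replicate check. A shared response that depends on the depth of the knockdown is therefore not excluded. Also open are an effect of the knockdown specific to MDA-MB-231 and a difference in culture or RNA preparation between its siCtrl and siNUP93 samples. The 2 libraries each cannot separate these.

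The second pattern is a narrower range of nuclear-to-cytosolic ratios in MCF7 under siNUP93, with an SD across 7766 genes of 1.07 under siCtrl and 0.94 under siNUP93, a ratio of 0.88. Trends with GC content and transcript length were removed from both, and the ratio stayed at 0.88 (95% bootstrap range over genes 0.87 to 0.90), which argues against that bias as the whole cause. This bears on the spread alone. Over 7732 genes, GC content had a Pearson r of -0.26 with the whole-cell change, 0.01 with the cytosolic and 0.22 with the nuclear change. The random lists were not matched on GC content. A GC bias therefore stays open for the whole-cell and nuclear lists and for the overlap with MDA-MB-231. Cytosolic RNA in the nuclear siNUP93 samples would by itself leave the cytosolic level of ribosomal protein mRNAs in place. Their median cytosolic log2 ratio was -0.36 (equally cytosolic random lists had -0.28), so such carry-over is not the whole cause. It is not excluded, because a cytosolic fall does not bear on what the nuclear samples held. In the nucleus ribosomal protein mRNAs had a median of 0.23, where equally cytosolic random lists had 0.31. Nuclear RNA in the cytosolic siNUP93 samples may play a part: a share of 5.72% would fit 614 nuclear-rich mRNAs, and with that share the median nuclear-retained noncoding RNA showed 0.0095 of the predicted rise (MALAT1 was at 245 TPM where 476 was predicted). That median and the summed rise, 0.194 of the predicted, lie under the bound of 0.25 set for excluding this carry-over. Of the 9 RNAs, however, PVT1 showed 0.733 and SNHG12, RMRP and JPX overshot at 2.99, 4.03 and 4.86. RMRP was also higher in whole-cell extracts (33.1 to 92.5 TPM), so its cytosolic rise need not come from carry-over. Its values are uncertain in any case, because it has no poly(A) tail. SNHG12 (3.485 to 6.92 TPM) and JPX (7.97 to 14.51 TPM) were low in the cytosol and not higher in whole-cell extracts. For that spread, a reason adopted after the values were seen, carry-over of nuclear RNA is kept open, though hardly borne out. The fitted share may also be too high, since the 614 mRNAs were picked by a high siCtrl ratio. That ratio shares its siCtrl cytosolic values with the fitted rise. Also open are cytosolic RNA in the nuclear samples, an effect of NUP93 on RNA distribution and larger random error in the siCtrl columns. No values per library were used to test the last of these.

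The third pattern is loss from the MCF7 cytosol without nuclear loss, as for SNHG19 and DPM3, which might come from cleavage of unintended transcripts by the siRNA pool. If so, such genes should also fall in MDA-MB-231, which the labels' protocols describe as transfected in the same way. Without these and NUP93, 62 genes had a centred cytosolic ratio of -1 or lower and a nuclear ratio of at least -0.5, and 35.5% of them (22 genes, 95% Wilson interval 24.7 to 47.9%) fell in MDA-MB-231, against 18.8% of 6041 other genes (Fisher's exact test, two-sided, p = 0.00179, across genes that are not independent). A further 10 of the 62 rose. LOXL1 and AKAP13, named above as cytosolic decreases, stayed among the 62, and both are among the 22 that fell. The shift was small, with a median MDA-MB-231 log2 fold change of -0.06 for the 62 genes and 0.03 for the others. Cleavage would also lower whole-cell levels in MCF7, which were not tested for the 62 as a set. Most of the 22 were lower there, among them UBE2S (761 to 368 TPM), TOMM7 (82.7 to 40.1 TPM) and EDF1 (493 to 345 TPM). GPN2 (24.2 to 54.5 TPM), U2AF1L4 and SAFB2 were higher, and FAM118A and NDUFAF8 were about level. The excess goes with the hypothesis, but a response to NUP93 loss shared by both lines would give the same excess. The siRNA sequences were not used here to part these explanations.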
